A study of Homo sapiens with 12 samples.

How the data were processed

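Total RNA of KYSE70 cells was extracted with a column kit and sequenced as standard Illumina libraries, 4 per group for the control, 10 µM pyrimethamine and 20 nM mitoxantrone at 72 h. The submitters' processing notes name FastQC 0.11.5, cutadapt 1.12, STAR 2.6.90c and featureCounts 1.5.1, and the genome builds hg38 and mm10. All gene identifiers in the deposited table are human. The deposited values are a normalized signal per gene and library, read counts that the authors divided by 1 factor per library. Every value was a whole number of reads once multiplied by its library's factor (100.0% within 0.01 read), and the factors equaled median-of-ratios size factors computed from the recovered reads. The tool that made the factors, the strand setting and the treatment of reads that overlap several genes are not stated in the sources used here.

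The table holds 58884 genes, of which 34033 had any read. Of the identifiers, 58611 were in GENCODE release 29 and 273 were not, and coordinates on GRCh38 were taken from that release, which may differ from the annotation the authors used. Gene identifiers were used to join tables, since 1685 symbols are repeated and 27 symbols read as dates. Library depth is the sum of recovered reads, 47.5 M to 94.5 M. A library with 0 reads of a gene allows up to 3 reads, which was used as the floor per library. Ratios of genes with 1 to 3 reads in a group carry a 95% counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

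Genes with a value of at least 10 in at least 4 of the 12 libraries were tested, 16950 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(value + 1) over all 12 libraries with group as the only term, with eBayes and a trend. Tests were two-sided and adjusted by Benjamini-Hochberg within each comparison, with calls at 0.05. The median standard error of a log2 change was 0.0719. A log2 change on this scale understates changes of genes with few counts, and folds are 2 to the power of the log2 change. The tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

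Of 40 fixed gene lists, covering drug targets, stress and signaling pathways, cell state and markers of other cell types, 38 had at least 3 tested members. They were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with the other genes, adjusted over the lists of each comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance and makes no comparison with other genes, were run beside it. Called members were counted over all genes and adjusted over the list alone. Library measures were compared with two-sided exact permutation tests.

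Genes named in each comparison were chosen by a rule. It takes 12 genes of the NRF2 pathway and 3 drug target genes always, of which not all are described. It adds the 10 highest rises and 10 largest falls among called genes with a mean of at least 50 in the higher group and no overlap between libraries, without genes that have no symbol, pseudogenes and antisense transcripts, as judged by the GENCODE gene type and the name. It also adds, for each list called by camera, the 4 called members with the largest change in the list's direction and the largest called change against it. Other genes, such as the remaining members behind small counts, were chosen after their values were seen, and so were the gene families in the last part.

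Alternatives were pseudocounts of 0.5 and 10, no filter, a mean of at least 100, libraries rescaled to the same total, upper-quartile rescaling, quantile normalization, a robust variance, no variance trend, only the 8 libraries compared, a block for the replicate number, and each library left out. edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered whole reads and called 9286 and 9318 genes for pyrimethamine against the control, 11765 and 11834 for mitoxantrone against the control, and 12943 and 12960 between the drugs. The tests were also tried on simulated data with 200 genes changed in each comparison. At a 1.5-fold change, 38, 37 and 34 of 50 genes were recovered in the same order. Over all unchanged genes, and not at this fold alone, 10, 8 and 7 were called falsely. Far fewer genes were changed there than were called in the data, so these counts do not show how many calls are false in the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.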

Results

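RNA was sequenced from KYSE70 cells, a human esophageal squamous cell carcinoma line, in 12 libraries. Of these, 4 came from untreated cells (control), 4 from cells given 10 µM pyrimethamine and 4 from cells given 20 nM mitoxantrone, each drug for 72 h. Pyrimethamine is an antifolate, best known from malaria and toxoplasmosis, and mitoxantrone is an anticancer drug that intercalates into DNA and poisons type II topoisomerases. The series title names both drugs as inhibitors of NRF2, the transcription factor encoded by NFE2L2 that drives antioxidant and detoxification genes. The comparisons ask which genes, NRF2 target genes among them, differed between each drug and the control and between the drugs. The labels do not say whether a vehicle was added to the control cells, or whether the 4 libraries of a group came from separate cultures. Every p-value therefore measures only the spread between samples that may be technical repeats.

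The libraries held 47.5 M to 94.5 M reads assigned to genes, with group means of 67.1 M (SD 19.8, n = 4) for the control, 65.4 M (SD 5.43, n = 4) for pyrimethamine and 65.9 M (SD 8.84, n = 4) for mitoxantrone. The first principal component held 69.4% of the variance and the second 10.1%, and the 4 libraries of each group lay together on both. The median coefficient of variation between replicates, over genes with a group mean of at least 100 normalized counts, was 4.46% in the control, 4.45% under pyrimethamine and 5.90% under mitoxantrone. Transcripts encoded by the mitochondrial genome took 6.43% ± 0.230 of reads in the control, 7.65% ± 0.621 under pyrimethamine and 3.71% ± 0.321 under mitoxantrone (SD, n = 4 each). Ribosomal protein genes took 5.67% ± 0.177, 5.95% ± 0.257 and 7.10% ± 0.462 of reads in the same order (SD, n = 4 each). Over 15 such tests of library measures, the mitochondrial share differed in every pair of groups (two-sided exact permutation p = 0.0286, the smallest that 70 arrangements can give, adjusted p = 0.0357). The ribosomal share differed with the same exact permutation p between mitoxantrone and each other group, but not between pyrimethamine and the control (exact permutation p = 0.143, adjusted p = 0.143). Within the mitoxantrone group, replicate 1 stood apart, with a mitochondrial share of 3.23% against 3.84% to 3.89% in the other 3 libraries.

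**Figure D1:**
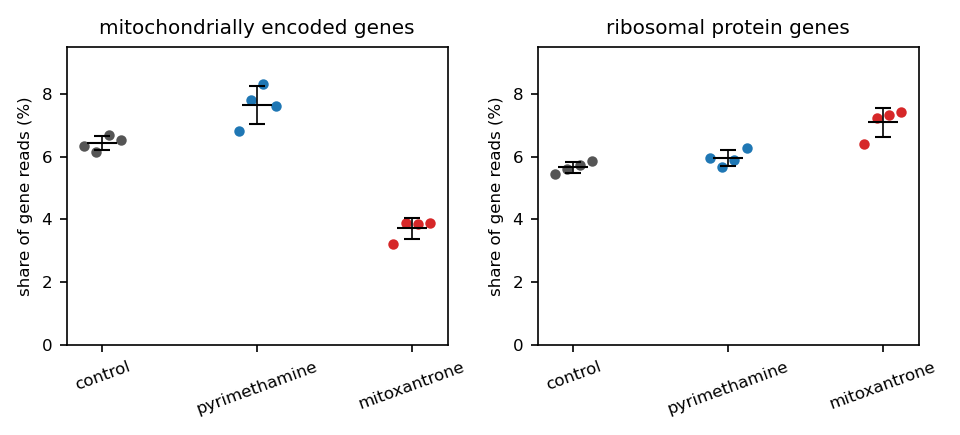
Share of gene reads, in percent, on mitochondrially encoded genes (left) and ribosomal protein genes (right) by group. Points are the 12 libraries, bars are the mean and SD (n = 4); the mitochondrial share was lowest under mitoxantrone, at 3.71%.

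NRF2 target genes were mostly lower under pyrimethamine than in the control. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, fell from 3254 ± 135 normalized counts in the control to 1527 ± 118 (SD, n = 4 each), 2.13-fold lower (adjusted p = 2.53e-12). AKR1B10, an aldo-keto reductase, fell from 11516 ± 373 to 7004 ± 233 normalized counts, 1.64-fold lower (adjusted p = 1.91e-11). SLC7A11, the cystine transporter that feeds glutathione synthesis, fell from 5183 ± 401 to 3328 ± 165 normalized counts, 1.55-fold lower (adjusted p = 4.33e-08). Of 43 NRF2 target genes tested, 28 were lower, 6 higher and 9 not called. Adjusted over the list alone, 30 were lower and 6 higher. Members named only because they make up a small count were chosen after their values were seen. The median log2 change of the list was -0.27 (camera adjusted p = 1.99e-04, and adjusted p = 0.254 with an estimated correlation). Other members that fell were GCLM, the modifier subunit of the enzyme that starts glutathione synthesis, with a log2 change of -0.27, TXNRD1, a thioredoxin reductase, with -0.13, and the oxidative enzymes CYP4F3 and ADH7, with -1.83 and -1.62. The 6 members that rose included ABCC3, an export pump, with a log2 change of 0.41, and PRDX1, a peroxiredoxin, with 0.29.

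NFE2L2 itself, on chromosome 2 at 177227595 to 177392697 of GRCh38, went from 4879 ± 189 to 4525 ± 165 normalized counts (SD, n = 4 each), a log2 change of -0.11 (adjusted p = 0.0389). This call was lost when control replicate 1, 2 or 3 or pyrimethamine replicate 1, 3 or 4 was left out, with adjusted p-values of 0.0557 to 0.134, and also with no filter on low values (0.0762), upper-quartile rescaling (0.0590) or no trend in the variance (0.0809). KEAP1, whose protein marks NRF2 for degradation (chromosome 19, 10486120 to 10503741), had a log2 change of -0.05 (adjusted p = 0.279), and the quinone reductase gene NQO1 (chromosome 16, 69706996 to 69726951) had -0.04 (adjusted p = 0.394). With each library rescaled to the same total, KEAP1 passed the test at -0.11 (adjusted p = 0.0234) and NQO1 at -0.10 (0.0262), and NQO1 also did under quantile normalization at -0.10 (0.0125). GCLC, the catalytic partner of GCLM, had a log2 change of 0.05 (adjusted p = 0.509), and AKR1C1 had 0.05 (adjusted p = 0.417). SRXN1, which repairs oxidized peroxiredoxins, had a log2 change of -1.65 at few reads (adjusted p = 0.00930), and 85.0% of its exon sequence overlaps other annotated genes. Its call was lost with a robust variance (adjusted p = 0.0774), without the variance trend (0.0690) and in DESeq2 (0.0629). Of 10 NRF2 pathway regulators, 4 (BACH1, MAFF, MAFK and NFE2L1) were higher, 2 (NFE2L2 and BTRC) lower and 4 (KEAP1, CUL3, RBX1 and SQSTM1) not called (camera adjusted p = 0.212).

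**Figure D2:**
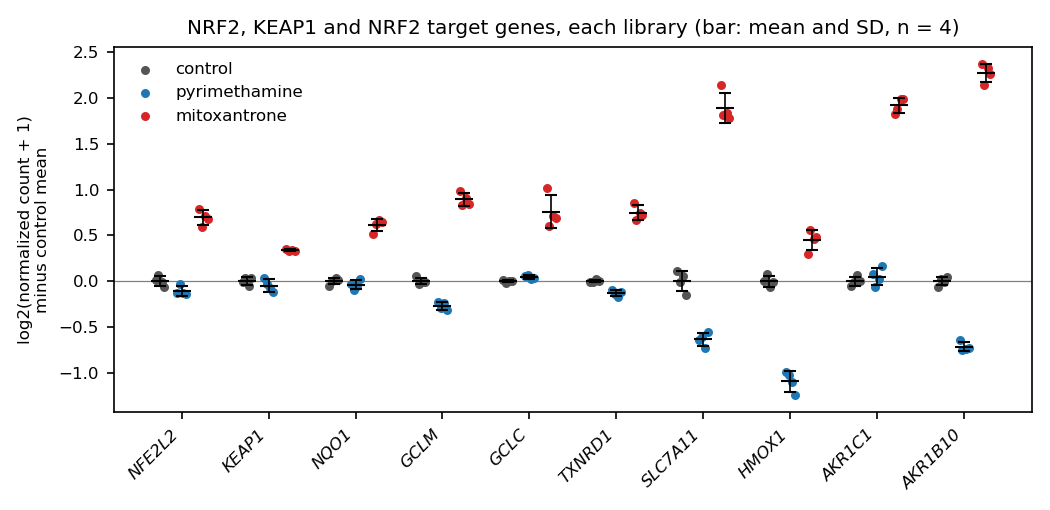
Level of NFE2L2, KEAP1 and NRF2 target genes in each of the 12 libraries, as log2(normalized count + 1) minus the mean of the control. Points are libraries and bars are the mean and SD (n = 4); HMOX1, AKR1B10 and SLC7A11 were lower under pyrimethamine and higher under mitoxantrone than in the control.

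Genes of cell division moved apart under pyrimethamine. Of 29 genes of G2/M and mitosis, 26 were higher, 0 lower and 3 (BUB1B, KIF11 and PRC1) not called, with a median log2 change of 0.55 (camera adjusted p = 1.37e-13, and adjusted p = 0.254 with an estimated correlation). KIF20A, a kinesin of cytokinesis, rose by a log2 change of 1.2, CENPE, a kinetochore motor, by 0.98, and AURKA, a spindle kinase, by 0.96. Of 29 genes of DNA replication and G1/S, 14 were lower, 3 (GINS2, E2F1 and POLE) higher and 12 not called, and 15 were lower and 3 higher adjusted over the list alone. Their median log2 change was -0.14 (camera adjusted p = 0.00152, and adjusted p = 0.254 with an estimated correlation). CCNE2, a cyclin of S-phase entry, fell with a log2 change of -0.95, LIG1, the ligase that joins Okazaki fragments, with -0.79, and CDT1, a licensing factor, with -0.62. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, were higher in 12 of 16 cases, lower in 0 and not called in 4 (HIST1H1D, HIST1H1E, HIST2H2AC and HIST1H4C). The median log2 change of these histone genes was 1.36 (camera adjusted p = 1.35e-04, and adjusted p = 0.150 with an estimated correlation), with 3.12 for HIST1H3B and 2.69 for HIST1H2BG, although reads of histone genes can fall on near-identical copies.

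Growth factor and mechanical signaling genes were mostly higher under pyrimethamine. Among 14 genes of EGFR and MAPK output, 12 were higher and 2 (SPRY2 and IER3) lower, with a median log2 change of 0.35 (camera adjusted p = 0.00215, and adjusted p = 0.254 with an estimated correlation). HBEGF and AREG, ligands of the EGF receptor, rose by log2 changes of 1.18 and 1.08. SPRY2, a feedback inhibitor of the pathway, fell with -0.39. Of 9 YAP target genes, 7 were higher, 1 (AXL) lower and 1 (AJUBA) not called, with a median of 0.41 (camera adjusted p = 0.0137, and adjusted p = 0.415 with an estimated correlation). CCN2, a matricellular protein gene, rose by 1.24 and F3, encoding tissue factor, by 0.77, while AXL, a receptor tyrosine kinase, fell with -0.32.

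Mitochondrially encoded transcripts were higher in 11 of 13 cases under pyrimethamine and not called in 2 (MT-CO1 and MT-ATP8), with a median log2 change of 0.30 (camera adjusted p = 0.0104, and adjusted p = 0.574 with an estimated correlation), beside a mitochondrial share of 7.65% against 6.43% of reads. Under quantile normalization the median was 0.17 and the call was lost (adjusted p = 0.198). MT-ND2 rose by 0.62 and MT-ND1 by 0.50. Nuclear genes of oxidative phosphorylation were higher in 13 of 22 cases, lower in 3 (NDUFS1, NDUFS3 and CYC1) and not called in 6, with a median of 0.16 (camera adjusted p = 0.0304, and adjusted p = 0.574 with an estimated correlation). That list lost its call when libraries were rescaled to the same total (median 0.10, adjusted p = 0.0668) and under quantile normalization (adjusted p = 0.105). Its members NDUFA2 and NDUFB3, of complex I, rose by 0.58 and 0.54, while NDUFS1, also of complex I, fell with -0.35. Ribosomal protein genes were higher in 17 of 31 cases, lower in 1 (RPL3) and not called in 13, with 18 higher and 1 lower adjusted over the list alone. Their median was 0.15 (camera adjusted p = 0.0137, and adjusted p = 0.652 with an estimated correlation), with 0.37 for RPL27 and -0.67 for RPL3. The median of the ribosomal protein list was 0.09 with libraries rescaled to the same total and 0.0063 under quantile normalization, with a mean of -0.0077, and there its call was lost (adjusted p = 0.700). With fry it did not pass either (adjusted p = 0.0878).

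Genes of the endoplasmic reticulum stress response were lower in 12 of 17 cases under pyrimethamine, higher in 0 and not called in 5 (HSP90B1, PDIA4, CALR, EDEM1 and ERN1), with a median log2 change of -0.18 (camera adjusted p = 0.00569, and adjusted p = 0.254 with an estimated correlation). HERPUD1, of the degradation pathway for misfolded proteins, fell with -0.68 and the transcription factor gene XBP1 with -0.46. Of 9 iron handling genes, 6 were lower, 0 higher and 3 (TFRC, NCOA4 and ACO1) not called, with a median of -0.30 (camera adjusted p = 0.00569, and adjusted p = 0.254 with an estimated correlation). STEAP3, an endosomal iron reductase, fell with -0.90, and HMOX1, which this list shares with the NRF2 list, with -1.09. Folate and one-carbon genes went both ways, with 7 of 22 higher, 9 lower and 6 not called (median -0.04, camera adjusted p = 0.499). Neither type I interferon genes nor p53 target genes were called as a list. Of 21 interferon genes, 8 were lower, 5 higher and 8 not called (camera adjusted p = 0.490), and of 25 p53 target genes, 12 were higher, 6 lower and 7 not called (camera adjusted p = 0.181). Counts adjusted over the list alone equaled those over all genes for every list given for pyrimethamine except where both are printed.

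Among single genes with a mean of at least 50 normalized counts in the higher group and no overlap between libraries, SCEL, encoding the cornified envelope precursor sciellin, rose most under pyrimethamine, with a log2 change of 4.49, followed by NPPB, a natriuretic peptide gene, with 3.74. DHRS2, a short-chain dehydrogenase, fell most by the same limits, from 221 ± 7.11 to 14.1 ± 4.25 normalized counts (SD, n = 4 each), a log2 change of -3.93. INHBE, an inhibin subunit gene, and NUPR1, a stress-induced nuclear protein gene, fell with -2.47 and -2.37. TOP2A rose by 0.44 and TOP2B fell with -0.61. Over all 16950 genes tested by limma, 4477 were higher and 4565 lower at an adjusted p under 0.05, 53.3% of those tested. At least 2-fold changes were seen in 738 higher and 398 lower genes, and in 712 and 585 under quantile normalization, 481 and 188 with a pseudocount of 10, and 165 and 119 among genes with a mean of at least 100 normalized counts; without a filter 1336 were higher. Of 38 lists tested, 11 were called by camera with the preset correlation, 7 higher and 4 lower, and 0 with an estimated correlation.

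NRF2 target genes were mostly higher under mitoxantrone than in the control. AKR1B10 rose from 11516 ± 373 normalized counts in the control to 55861 ± 3766 (SD, n = 4 each), 4.84-fold higher (adjusted p = 1.06e-19). SLC7A11 rose from 5183 ± 401 to 19295 ± 2314 normalized counts, 3.71-fold higher (adjusted p = 5.01e-16). NFE2L2 rose from 4879 ± 189 to 7899.8 ± 432 normalized counts, 1.62-fold higher (adjusted p = 6.54e-12). Of 43 NRF2 target genes, 36 were higher, 3 (ABCC2, ABHD4 and BLVRB) lower and 4 (ABCC3, CBR3, UGT1A6 and UGDH) not called, with the same counts adjusted over the list alone. Their median log2 change was 0.72 (camera adjusted p = 1.67e-10, and adjusted p = 0.0729 with an estimated correlation), and 0.48 under quantile normalization. Log2 changes of other members were 1.92 for AKR1C1, 0.89 for GCLM, 0.76 for GCLC, 0.75 for TXNRD1, 0.61 for NQO1 and 0.45 for HMOX1. AKR1C1 and AKR1B10 have near-identical relatives, which limits how surely reads were assigned to either. ABHD4, a lipid hydrolase, fell with -0.40. KEAP1 also rose, by a log2 change of 0.34 (adjusted p = 4.68e-08). SRXN1 had 1.52 (adjusted p = 0.0113), a call lost with a robust variance (0.0817) or without the variance trend (0.0725).

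Interferon and antigen presentation genes fell under mitoxantrone. Of 21 type I interferon response genes, 19 were lower, 1 (BST2) higher and 1 (IFIH1) not called, with a median log2 change of -2.15 (camera adjusted p = 9.14e-08, and adjusted p = 0.00511 with an estimated correlation). This was the only list for mitoxantrone against the control that camera called with an estimated correlation. IFI44 fell with a log2 change of -4.42 and OAS2, a sensor of double-stranded RNA, with -3.54, whereas BST2, which tethers budding viruses, rose by 0.33. SAMD9L, an antiviral factor, held 3 reads over the mitoxantrone libraries and 142 over the controls, a ratio of 43.3 (95% counting interval 14.5 to 212.6). MHC class I antigen presentation genes were lower in 14 of 15 cases, higher in 0 and not called in 1 (ERAP2), with a median of -0.95 (camera adjusted p = 2.22e-05, and adjusted p = 0.176 with an estimated correlation). HLA-F, a non-classical class I gene, fell with -2.53, and PSMB8 and PSMB9, subunits of the immunoproteasome, with -2.43 and -1.70. The level of HLA-F was low, at 37.4 normalized counts in control replicate 1 and 15.8 to 17.8 in the other control libraries. Of 32 squamous differentiation genes, only 14 passed the filter and were tested. Of these, 11 were lower, 0 higher and 3 (KRT10, SPRR1B and EMP1) not called. Their median was -0.70 (camera adjusted p = 0.00716, and adjusted p = 0.104 with an estimated correlation). OVOL1, a differentiation factor, fell with -3.25 and TGM1, the transglutaminase of the cornified envelope, with -2.39.

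Genes of the ATF4 response, lipid synthesis and the ribosome were mostly higher under mitoxantrone. Of 20 genes of ATF4 and the amino acid response, 16 were higher, 2 (ATF3 and ATF5) lower and 2 (VLDLR and CTH) not called, with a median log2 change of 0.62 (camera adjusted p = 0.00270, and adjusted p = 0.176 with an estimated correlation). ATF4, the central transcription factor of this response, rose by 1.46 and TRIB3, a pseudokinase gene, by 1.22, while ATF3 fell with -0.88. Cholesterol synthesis genes were higher in 14 of 22 cases, lower in 1 and not called in 7, with a median of 0.41 (camera adjusted p = 0.00797, and adjusted p = 0.568 with an estimated correlation). Fatty acid synthesis genes were higher in 7 of 9 cases, lower in 1 (ACLY) and not called in 1 (FASN), with a median of 0.39 (camera adjusted p = 0.0208, and adjusted p = 0.526 with an estimated correlation). INSIG1, a sterol sensor partner, rose by 1.26 and SREBF1, the lipogenic transcription factor, by 1.55. All 31 ribosomal protein genes were higher, with a median of 0.44 (camera adjusted p = 3.55e-08, and adjusted p = 0.526 with an estimated correlation), beside a ribosomal share of 7.10% against 5.67% of reads. Under quantile normalization this median was 0.19. RPL5 rose by 0.69 and RPL4 by 0.64. Ribosome biogenesis genes were higher in 13 of 19 cases, lower in 5 (POLR1A, POLR1B, RRN3, PES1 and RRP12) and not called in 1 (NOLC1), with a median of 0.29 (camera adjusted p = 0.0328, and adjusted p = 0.526 with an estimated correlation) and 0.75 for NOP56, a nucleolar RNA-binding protein gene. This median was 0.18 with libraries rescaled to the same total and 0.16 under quantile normalization, where the call was lost (adjusted p = 0.274). The latter list also lost its call without mitoxantrone replicate 2 (adjusted p = 0.0517) and over genes with a mean of at least 100 normalized counts (0.0956), and the fatty acid list did so over the same genes (0.0617) and under quantile normalization (adjusted p = 0.0746).

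Mitochondrially encoded transcripts fell under mitoxantrone in 13 of 13 cases, with a median log2 change of -0.66 (camera adjusted p = 2.83e-04, and adjusted p = 0.526 with an estimated correlation), beside a mitochondrial share of 3.71% against 6.43% of reads. MT-ND1 fell with -1.28 and MT-CO1 with -0.81. Nuclear genes of oxidative phosphorylation were higher in 12 of 22 cases, lower in 1 (NDUFS3) and not called in 9, with a median of 0.15 (camera adjusted p = 0.0208, and adjusted p = 0.526 with an estimated correlation). CYC1, of complex III, rose by 0.56 and COX7C, of complex IV, by 0.54. This list lost its call with libraries rescaled to the same total (median 0.05, adjusted p = 0.0564), under quantile normalization (adjusted p = 0.215) and over genes with a mean of at least 100 (0.0769). G2/M and mitosis genes were higher in 24 of 29 cases, lower in 4 (CDK1, KIF20A, CDC25C and NEK2) and not called in 1 (NUSAP1), or 25 higher and 4 lower adjusted over the list alone. Their median was 0.34 (camera adjusted p = 3.62e-04, and adjusted p = 0.526 with an estimated correlation). CENPE rose by 1.14 and CENPF by 0.65, while KIF20A fell with -0.49.

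p53 target genes were not called as a list under mitoxantrone (12 higher, 7 lower and 6 not called of 25, 13 and 7 called adjusted over the list alone, camera adjusted p = 0.552). Their median log2 change was 0.12 and their mean -0.05, so the list went both ways. CDKN1A, the p53-induced cell cycle inhibitor, fell with a log2 change of -1.05 and MDM2, the p53 ubiquitin ligase, rose by 0.47, both named after their values were seen. Of 8 topoisomerase genes and partners, 5 (TOP1MT, TOP2A, TOP2B, TDP1 and TDP2) were higher and 1 (TOP3B) lower, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.142). TOP2B, a target of mitoxantrone, rose by 0.57 (adjusted p = 4.58e-09) and TOP2A by 0.14 (adjusted p = 0.00356). The TOP2A call was lost with libraries rescaled to the same total (adjusted p = 0.461) and under quantile normalization (0.852). Replication-dependent histone genes went both ways, with 9 higher and 6 lower of 16 (camera adjusted p = 0.552). For the lists given for mitoxantrone against the control, counts adjusted over the list alone equaled those over all genes except where both are printed.

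Markers of other cell types were measured as a check of the line. Of 10 fibroblast markers, 4 were tested, and 3 (COL1A1, PDGFRB and THY1) of these were lower under mitoxantrone, with a median log2 change of -1.41 (camera adjusted p = 0.0465, and adjusted p = 0.494 with an estimated correlation). COL1A1, a collagen chain, fell from 14955 to 4430.1 normalized counts and THY1, a surface glycoprotein, from 6334 to 3038, while COL3A1 was not called and COL1A2, COL6A3 and FAP were listed at 0 in the control and under mitoxantrone. The call of this list was lost without control replicate 1, any 1 pyrimethamine library or mitoxantrone replicate 3 or 4 (adjusted p = 0.0501 to 0.0563). The call of PDGFRB, which held 11.3 normalized counts in the control and 2.17 under mitoxantrone, was lost under quantile normalization (adjusted p = 0.0738). The call of the list was also lost with libraries rescaled to the same total (0.0601) and over genes with a mean of at least 100 (0.0617). Fibroblast markers under pyrimethamine were higher in 1 (THY1) and lower in 2 (COL1A1 and COL3A1) of 4 cases (camera adjusted p = 0.641). Of the endothelial markers, VWF fell from 1001.2 to 217.45 normalized counts under mitoxantrone and TEK from 20.2 to 8.68. Of the immune markers, LAPTM5 fell from 30.05 to 6.73, and PTPRC was not called, at 4.91 in the control and 3.01 under mitoxantrone; these lists had 2 tested members each, too few for camera. Under pyrimethamine PTPRC was higher, at 21.1, and TEK at 47.9, LAPTM5 was lower, at 6.17, and VWF was not called, at 1097.9.

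Single genes changed further under mitoxantrone. FGF21, a secreted metabolic hormone gene, rose by a log2 change of 4.04, and INHBE rose from 86.0 ± 11.9 to 1037 ± 159.9 normalized counts (SD, n = 4 each), a log2 change of 3.58. SAA1, an acute-phase protein gene, fell from 503 ± 55.0 to 9.45 ± 8.22, a log2 change of -5.93, and ACSL5, a fatty acid activating enzyme, fell with -5.42. APOL1, an apolipoprotein gene, fell with -4.99. GGTLC2 held 1 read over the mitoxantrone libraries against 219 over the controls, a ratio of 200.5 (95% counting interval 35.6 to 7954). Over 16950 genes, 5681 were higher and 6064 lower, 69.3% of those tested, and at least 2-fold changes were seen in 657 higher and 2343 lower genes. Under quantile normalization the 2-fold counts were 1260 higher and 1504 lower, 45.6% higher against 21.9%, and among genes with a mean of at least 100 they were 292 and 775; with a pseudocount of 10, 434 were higher. With libraries rescaled to the same total, 4420 genes were higher and 7210 lower. Of 38 lists, 13 were called by camera, 8 higher and 5 lower, and 1 with an estimated correlation. Without mitoxantrone replicate 1, the library that stood apart, 5658 genes were higher and 6059 lower, with 637 and 2328 changed at least 2-fold.

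**Figure D3:**
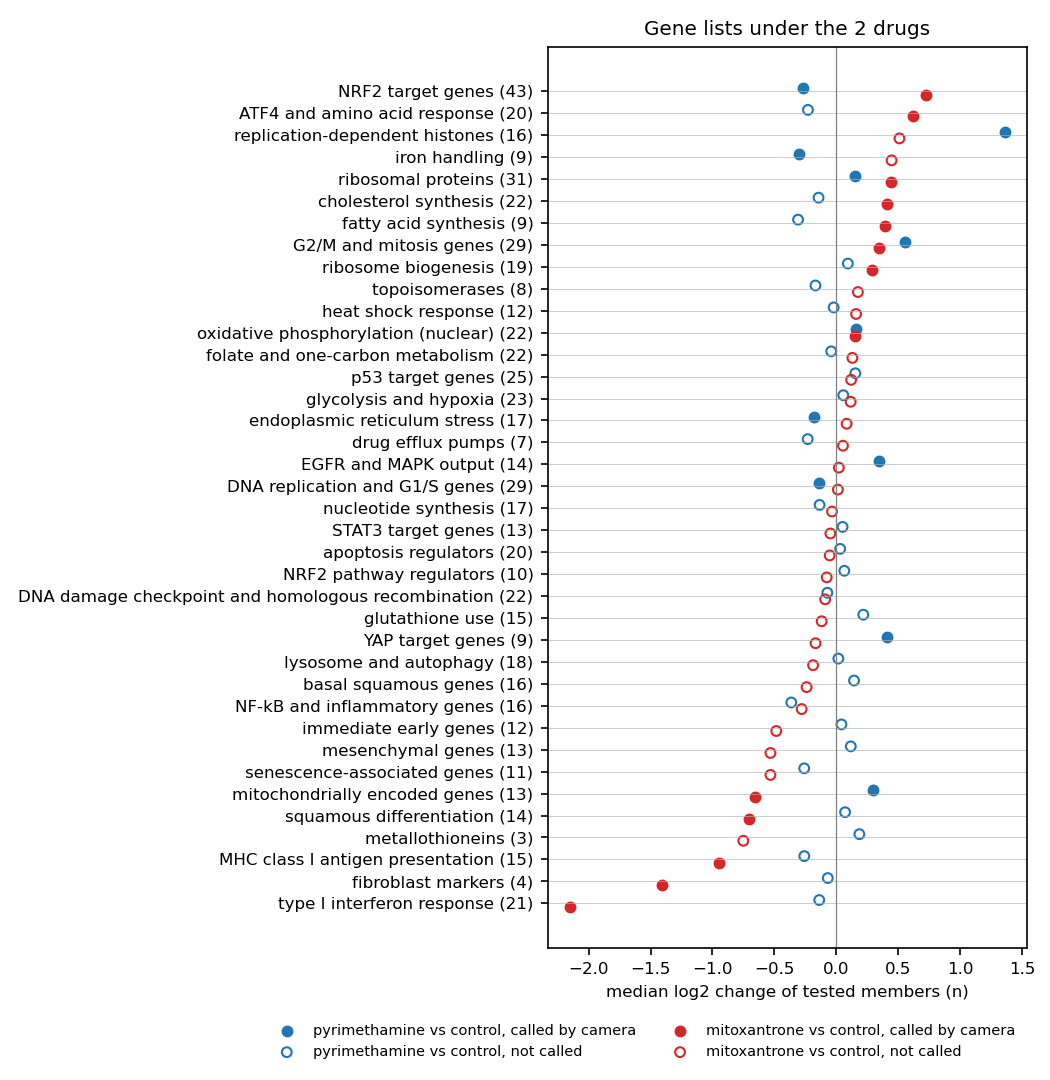
Median log2 change of the tested members of each gene list under each drug against the control, with the number of tested members in parentheses. Filled points were called by camera with the preset correlation and open points were not; NRF2 target genes had a median of -0.27 under pyrimethamine and 0.72 under mitoxantrone.

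Set directly against pyrimethamine, mitoxantrone cells held more NRF2 target transcripts. Of 43 NRF2 target genes, 39 were higher under mitoxantrone, 3 (ABCC2, ABCC3 and ABHD4) lower and 1 (BLVRB) not called, with the same counts adjusted over the list alone. The median log2 difference was 0.77 (camera adjusted p = 4.50e-11, and adjusted p = 0.0624 with an estimated correlation). HMOX1 was 2.91-fold higher, at 4442 ± 331 against 1527 ± 118 normalized counts (SD, n = 4 each; adjusted p = 5.05e-16). Log2 differences were 2.99 for AKR1B10, 2.53 for SLC7A11, 1.87 for AKR1C1, 1.16 for GCLM, 0.88 for TXNRD1, 0.80 for NFE2L2, 0.71 for GCLC, 0.65 for NQO1, 0.39 for KEAP1 and 3.17 for SRXN1. ABHD4 was lower, with -0.63.

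Genes of the ATF4 response were higher under mitoxantrone than under pyrimethamine in 15 of 20 cases and lower in 5 (ATF3, ATF5, VLDLR, SLC7A5 and CTH), with a median log2 difference of 1.09 (camera adjusted p = 0.0141, and adjusted p = 0.313 with an estimated correlation). NUPR1 differed by 2.79 and ATF4 by 2.70, against -1.72 for ATF3. Endoplasmic reticulum stress genes were higher in 12 of 17 cases and lower in 2 (CALR and CRELD2), with a median of 0.25 (camera adjusted p = 0.0214, and adjusted p = 0.471 with an estimated correlation) and 1.21 for XBP1. Iron handling genes were higher in 7 of 9 cases and lower in 2 (NCOA4 and ACO1), with a median of 0.64 (camera adjusted p = 0.0214, and adjusted p = 0.313 with an estimated correlation) and 1.44 for STEAP3. Cholesterol synthesis genes were higher in 16 of 22 cases and lower in 2, with a median of 0.49 (camera adjusted p = 0.00417, and adjusted p = 0.540 with an estimated correlation). Fatty acid synthesis genes were higher in 7 of 9 cases and lower in 1 (ACLY), with a median of 0.67 (camera adjusted p = 0.0188, and adjusted p = 0.540 with an estimated correlation). INSIG1 differed by 2.03 and SREBF1 by 2.55. Ribosomal protein genes were higher in 26 of 31 cases and lower in 0, or 27 and 0 adjusted over the list alone, with a median of 0.25 (camera adjusted p = 4.03e-04, and adjusted p = 0.540 with an estimated correlation) and 1.25 for RPL3. The ribosomal median was 0.13 under quantile normalization, where the calls of endoplasmic reticulum stress genes (adjusted p = 0.123) and iron handling genes (0.0519) were lost. Over genes with a mean of at least 100, calls were lost for ATF4, squamous and iron genes (adjusted p = 0.0570 each), endoplasmic reticulum stress genes (0.0709) and fatty acid genes (0.0538).

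Interferon genes were lower under mitoxantrone than under pyrimethamine in 18 of 21 cases and higher in 2 (IFIH1 and BST2), with a median log2 difference of -2.14 (camera adjusted p = 9.36e-05, and adjusted p = 0.0279 with an estimated correlation), the only list that an estimated correlation left called here. OAS2 differed by -4.47. IFIH1, a sensor of viral RNA, was higher by 0.98. The call of IFIH1 was lost without pyrimethamine replicate 2 (adjusted p = 0.0824) or 3 (0.0643) or mitoxantrone replicate 3 (0.0796), with no filter (0.0752) and in edgeR (0.0527). MHC class I genes were lower in 10 of 15 cases and higher in 1 (ERAP1), with a median of -0.72 (camera adjusted p = 0.0182, and adjusted p = 0.540 with an estimated correlation) and -1.24 for HLA-B. Of 32 squamous differentiation genes, 14 were tested, and 9 of these were lower and 1 (GRHL3) higher. Their median was -0.79 (camera adjusted p = 0.0244, and adjusted p = 0.249 with an estimated correlation), with -2.97 for TGM1. YAP target genes were lower in 7 of 9 cases and higher in 1 (AJUBA), with a median of -0.44 (camera adjusted p = 0.0441, and adjusted p = 0.540 with an estimated correlation) and -2.27 for CCN2. The YAP call was lost without control replicate 4 (adjusted p = 0.0513) and with libraries rescaled to the same total (0.0528).

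G2/M and mitosis genes were lower under mitoxantrone than under pyrimethamine in 19 of 29 cases and higher in 3 (CCNB1, BUB1B and KIF11), with a median log2 difference of -0.29 (camera adjusted p = 0.0141, and adjusted p = 0.540 with an estimated correlation). KIF20A differed by -1.69 and CDK1, the mitotic kinase, by -0.83. Mitochondrially encoded transcripts were lower in 13 of 13 cases, with a median of -0.96 (camera adjusted p = 3.06e-04, and adjusted p = 0.540 with an estimated correlation), beside shares of 3.71% and 7.65% of reads. TOP2B was higher under mitoxantrone by 1.19 and TOP2A lower, at -0.30. INHBE differed by 6.05 and DHRS2 by 4.85, while SAA1 was lower, at -7.08. Over 16950 genes, 6255 were higher and 6701 lower under mitoxantrone, 76.4% of those tested, with at least 2-fold differences in 1367 and 2898, in 2101 and 2113 under quantile normalization, and in 798 and 1055 among genes with a mean of at least 100; without a filter 4547 were lower. Of 38 lists, 13 were called by camera, 7 higher and 6 lower, and 1 with an estimated correlation. Where 1 count is printed for a list in the direct comparison of the drugs, it was the same adjusted over the list alone.

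The drugs moved many genes in opposite directions. Of the 16950 genes tested, 4392 were called in opposite directions against the control, 2141 higher under pyrimethamine and lower under mitoxantrone and 2251 the other way, where independent lists of these sizes would share 3132. Calls in the same direction numbered 2400, 1204 higher and 1196 lower, where independent lists would share 3134. At least 2-fold changes in opposite directions were seen in 475 genes, 396 of them higher under pyrimethamine, against 127 in the same direction. Among genes with a mean of at least 100 normalized counts, 126 changed at least 2-fold in opposite directions. HMOX1, AKR1B10, SLC7A11, GCLM, TXNRD1 and INHBE were among the genes that fell under pyrimethamine and rose under mitoxantrone. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of -0.246 and a Spearman correlation of -0.219, and a Pearson correlation of -0.151 under quantile normalization. Shared controls alone push this value up, to a Pearson correlation of 0.5002 (0.466 to 0.543) and a Spearman correlation of 0.437 in 100 simulations of unchanged groups. The covariance was -0.129, against 0.0261 in these simulations. With the controls split 2 and 2 between the drugs, the Pearson correlation was -0.277 on average over 6 splits (-0.293 to -0.262).

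**Figure D4:**
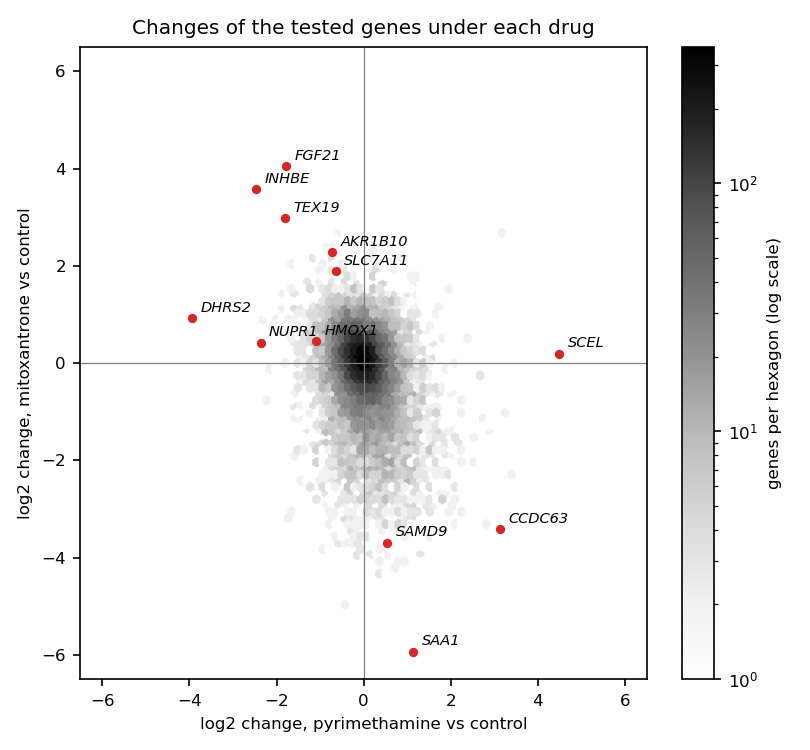
Log2 change under mitoxantrone (vertical axis) against log2 change under pyrimethamine (horizontal axis), each relative to the control, for the 16950 genes tested. Gray hexagons are shaded by the number of genes on a log scale and red points are single genes; the Pearson correlation across genes was -0.246.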

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

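The 3 patterns weighed here were picked after the main comparisons had been seen, and quantile normalization for the lists and the overlap and left-out libraries for the overlap were tests chosen only after the result was seen. In 43 cases, 1 of the 4 libraries of a group stood apart from the other 3 by Dixon's ratio. This is the gap to the nearest library divided by the whole range, so a high ratio can go with a small gap. In pyrimethamine replicate 4, for example, DUSP4 held 1602 normalized counts, against 1669 to 1674 in the other libraries of the group. Of 537 gene and group combinations scanned, 41 passed, where chance alone gives 26.85, and of 15 library measures 2 passed, where chance gives 0.75.

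Mitoxantrone replicate 1 held 18 of the 41. It was the lowest library, with ratios of 0.852 for MT-ND2, 0.898 for MT-ND1, 0.920 for MT-CYB, 0.931 for RPL14, 0.891 for RPL8, 0.881 for RPL3, 0.869 for FGF21, 0.983 for RPL4, 0.931 for RPL7A, 0.903 for NPM1 and 0.946 for RPL10A. It was the highest, with ratios of 0.853 for SLC7A11, 0.883 for TOP2B, 0.867 for SPRY2, 1 for GGTLC2, 0.897 for PRC1, 0.939 for SREBF1 and 0.906 for KIF11. It was also lowest in the share of reads on mitochondrially encoded genes (ratio 0.934, 3.23% against 3.84% to 3.89%) and on the 10 most abundant genes (ratio 0.964, 5.02% against 5.63% to 5.65%). Mitoxantrone replicate 2 stood apart with 0.895 for SYNPO2L, 0.962 for APOL1, 0.865 for PDGFRB and 0.883 for SERPINA9, replicate 3 with 0.868 for TMEM52B, and replicate 4 with 1 for CCDC63 and 0.848 for VSTM1. These 7 genes had under 10 normalized counts in every mitoxantrone library.

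Pyrimethamine replicate 4 stood apart with 0.856 for HIST1H2BC, 0.933 for DUSP4, 0.864 for MAMDC4, 0.843 for SREBF2 and 0.855 for NPM1. Pyrimethamine replicate 1 did so with 0.846 for AKR1B10, 0.935 for ZNF750 and 0.836 for RRP12, replicate 2 with 0.969 for NFE2L2, and replicate 3 with 0.920 for CYP4F3 and 0.870 for KIF20A. Control replicate 1 stood apart with 0.888 for LINC01003 and 0.906 for HLA-F, replicate 2 with 0.908 for DDIT3, and replicate 4 with 0.874 for IFI44 and 0.851 for NDUFS3.

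NRF2 target genes were higher under mitoxantrone, with a mean log2 change of 0.75. Library scaling as the whole cause is argued against by the lowest mean over 3 other scalings, 0.650 under quantile normalization. The list was called by camera there (adjusted p = 8.40e-08), although the median fell from 0.72 to 0.48. Rescaling to the same total or by upper quartile gave means of 0.651 and 0.705. Those rescalings shift all genes nearly alike, and camera compares a list with the other genes, so its calls under them add little. Leaving out AKR1C1, AKR1C2, AKR1C3, AKR1B10, UGT1A6, TRIM16, TRIM16L, FTL and FTH1 left 34 members, whose mean was 0.632 (camera adjusted p = 1.23e-07). This argues against reads shared between near-identical copies of the genes left out as the whole cause. The genes were chosen by name and not by comparing sequences, so members with close copies may remain among the 34. Removing the trend on GC content, gene length and mean level left 0.707 (SE over genes 0.0991). An effect of the drug on these genes is a hypothesis, and with an estimated correlation the list did not pass (adjusted p = 0.0729).

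Type I interferon and MHC class I genes were lower under mitoxantrone, with a mean log2 change of -1.67 over 36 genes. The mean nearest to 0 over 3 other scalings was -1.38, under quantile normalization, which argues against library scaling as the whole cause. Rescaling to the same total or by upper quartile shifts all genes nearly alike and gave -1.76 and -1.71, further from 0. The 26 members with a mean of at least 100 normalized counts had a mean of -1.34 (SE 0.206), and 25 of them were called lower. This argues against genes near the floor. The SE here is taken over genes, which are not independent replicates. Removing the trend on GC content, length and mean level left -1.40 (SE over genes 0.196). A drug effect stays a hypothesis, found and tested on the same libraries.

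The drugs changed 475 genes at least 2-fold in opposite directions. The lowest count of opposite calls with split controls was 3525, which decides nothing about shared controls, since these push calls the same way (simulated Pearson correlation 0.5002). Without mitoxantrone replicate 1 the 2-fold count was 472, which argues against that library as the cause. Under quantile normalization it was 377, a ratio of 0.794 to the count as deposited and just under 0.8, a limit written before the count under quantile normalization was seen, so a contribution of library scaling to the number of genes stays open and cannot be told apart from a drug effect.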

How the results depend on the processing

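Quantile normalization for the lists and the overlap and left-out libraries for the overlap were chosen after seeing the data; the other alternatives were planned. No call reversed. Of 6661 values of named genes, 6628 kept their side of the threshold, 30 lost the call and 3 gained it. Direction was compared only where a value was called, so uncalled values among the 6628 could change sign. For lists, 710 of 777 values kept the call and 67 lost it, 35 of them with an estimated correlation and 8 under quantile normalization. With an estimated correlation only 2 of 37 list calls were kept. The correlation alone does not account for these losses. For squamous genes under mitoxantrone against the control it was estimated at -0.0047, below the preset 0.01. Their unadjusted camera p still went from 0.00151 to 0.00821. The 777 values include a setting that could change few lists, since leaving out near-identical copies altered the NRF2 list only. The cause was not tested unless stated.

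Counts of genes changed at least 2-fold moved under several settings. With a pseudocount of 10, which shrinks changes of low genes, pyrimethamine gave 481 higher and 188 lower, and mitoxantrone 434 higher. Without a filter, with more genes tested, pyrimethamine gave 1336 higher and mitoxantrone against pyrimethamine 4547 lower. With a mean of at least 100, 12097 of the 16950 genes were tested. The counts were then 165 and 119 for pyrimethamine, against 738 and 398 in the main test. For mitoxantrone they were 292 and 775, against 657 and 2343, and between the drugs 798 and 1055, against 1367 and 2898. Opposite 2-fold changes numbered 126, against 475, with a Pearson correlation of -0.308. Most 2-fold calls against the control, and most opposite ones, were thus in genes below that mean. Quantile normalization gave 1260 and 1504 for mitoxantrone, 2101 higher between the drugs, and correlations of -0.151 (Pearson) and -0.180 (Spearman). The higher share of 2-fold calls went from 21.9% to 45.6% for mitoxantrone. With libraries rescaled to the same total, the share of calls that were higher went from 48.4% to 38.0% for mitoxantrone and from 49.5% to 39.8% for pyrimethamine.

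With an estimated correlation 0, 1 and 1 lists were called in the order of the report, and with fry 32, 35 and 36. NRF2 target genes then had means of -0.34 (adjusted p = 0.254), 0.75 (0.0729) and 1.09 (0.0624). Leaving out single libraries gave 4099 to 4767 higher and 4200 to 4806 lower genes for pyrimethamine, 5420 to 5681 and 5773 to 6059 for mitoxantrone, 6070 to 6261 and 6491 to 6720 between the drugs, and 3949 to 4619 opposite calls.

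Replicate numbers did not pair libraries: correlations of residuals at the same number were -0.0133 to 0.0295, against -0.0745 to 0.0446 at other numbers, and 4 of 12 libraries correlated best with their own number. A block for the number gave 4492 and 4565, 5685 and 6064, and 6237 and 6694 higher and lower genes, and the YAP list lost its call between the drugs (adjusted p = 0.0617). At a 1.2-fold change, 27, 14 and 17 of 50 simulated genes were recovered. Depth limits genes with few reads, such as GGTLC2, whose ratio of 200.5 has a counting interval of 35.6 to 7954.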

Other observations

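The gene families here, 176 formed from symbol stems, were looked at only after the data had been seen, and the tests of mitochondrial and zinc finger genes and the sorting of splits by libraries exchanged were chosen after the result was seen. SRSF genes, which encode serine- and arginine-rich splicing factors, rose under mitoxantrone, with 11 of 12 higher and a median log2 change of 0.68 (camera adjusted p = 0.000382; adjusted p = 0.390 with an estimated correlation). SRSF2 rose from 6132 ± 302 to 14633 ± 925 normalized counts (SD, n = 4 each), a log2 change of 1.25, against -0.13 under pyrimethamine. SRSF4 and SRSF3 rose by 1.06 and 0.77 under mitoxantrone and had -0.62 and -0.39 under pyrimethamine. Genes with EIF symbols, most of them translation initiation factors, were higher in 35 of 52 cases and lower in 5, EIF2B1, EIF4EBP2, EIF2AK3, EIF3C and EIF6 (median 0.24, camera adjusted p = 0.000382; adjusted p = 0.566 with an estimated correlation), with medians of 0.14 after rescaling to the same total and 0.16 under quantile normalization.

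Genes with MMP symbols, most of them encoding matrix metalloproteinases (MMP24OS, an opposite-strand gene, is among them), were lower under mitoxantrone in 13 of 14 cases, with a median log2 change of -1.65 (camera adjusted p = 0.00244; adjusted p = 0.390 with an estimated correlation) and of -1.08 under quantile normalization. MMP10, a stromelysin gene, fell with -1.93 and MMP17 with -1.44. Keratin genes were lower in 18 of 26 cases and higher in 0, with a median of -0.67 (camera adjusted p = 0.00631; adjusted p = 0.390 with an estimated correlation). KRT75 fell with -2.81 and KRT19, a simple epithelial keratin gene, with -2.06. The directions of the SRSF, EIF, MMP and keratin families under mitoxantrone held under quantile normalization. They also held when libraries were rescaled to the same total or by upper quartile. Those rescalings shifted the median log2 change of all genes by only -0.0998 and -0.0460, too little to turn these family medians.

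Zinc finger genes with ZNF symbols were higher under mitoxantrone in 166 of 364 cases and lower in 60 (median 0.19, camera adjusted p = 0.00979; adjusted p = 0.40 with an estimated correlation), with medians of 0.09 after rescaling to the same total and 0.29 under quantile normalization. A hypothesis was that this reflects a shift of chromosome 19, which holds many of them. The 216 ZNF genes outside that chromosome include the read-through gene ZNF670-ZNF695 that the family above leaves out. Their mean log2 change was 0.176 (SE over genes 0.0321), near the 0.156 (SE over genes 0.0413) of the 149 on it. This argues against such a shift as the whole cause. Chromosome 19 did have the highest median of the chromosomes compared, 0.153 over 771 genes with a mean of at least 100, ZNF genes among them. Its 658 other genes at that level, outside the ZNF family, had a mean log2 change of 0.0578 (SE over genes 0.0232). A further hypothesis was that transcripts of long genes fell under mitoxantrone. The Spearman correlation between genomic span and log2 change was -0.0168 across 12090 genes, which are not independent replicates, and this argues against it. Another was that the whole respiratory chain fell with the mitochondrial transcripts. The nuclear genes of oxidative phosphorylation had a mean log2 change of 0.199, against a fall of every mitochondrially encoded gene tested, which argues against it.

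Other splits of the 8 libraries of a comparison into groups of 4 were counted, 35 with the real one. Counts of changed genes as large as the real 9042, 11745 and 12956 came from 1 split each, the real one. The highest of the others were 0, 1 and 0. The real split thus ranked first of 35, the lowest share these splits can give. A split with exchanged libraries puts the group difference into the spread within groups, so the gap in counts adds nothing to the rank. The rank alone does not exclude chance, and it says nothing of differences between single cultures. For the number of called lists, 4 of 35 splits reached the real 11 for pyrimethamine and 2 of 35 the real 13 for mitoxantrone, with 13 the highest of the others in both, so by this count chance cannot be excluded. Every other split that reached the real number had exchanged 1 library of each group and so kept part of the difference between the groups, and splits with 2 exchanged gave at most 4 and 5 called lists, so the count of splits does not show that chance made the lists. Between the drugs, 1 of 35 splits, the real one, reached the real 13, with 10 the highest of the others. This is again the lowest share that 35 splits can give, and it does not exclude chance.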
